A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

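Ribosome profiling, the sequencing of mRNA fragments covered by ribosomes, had been done on 2 replicate libraries of the haploid yeast strain BY4742, grown to mid-exponential phase in synthetic medium and treated with cycloheximide, an inhibitor of translation elongation, at 50 µg/mL. The libraries were made with a small RNA kit, per the labels' protocols. The labels do not say whether the replicates came from separate cultures, so a difference between them may be technical. Both belong to 1 group, and no test between conditions exists.

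For each library the deposited values are raw counts of reads, per the file headers, in a table of 6666 annotated coding sequences (CDSs) and a table of 78989 intergenic open reading frames (IGORFs). Cutadapt, Bowtie and SAMtools and the genome build sacCer3 are named without versions, per the submitters' processing notes. The annotation, the counting tool, the handling of reads with several positions and any selection by read length or reading frame are not given in the sources used here. Such steps decide which reads reach each table, so the share of reads in IGORFs is a share of the counted reads and not of all ribosome footprints.

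The IGORF identifiers give chromosome, strand, start, end and frame. All 78989 run from the codon after a stop to the next stop codon in the R64 reference sequence, so they were read as 1-based coordinates on it. Gene symbols, coding lengths and positions came from the R64 annotation, in which 5993 of the 6666 CDS identifiers were found. The other 673 have no position or length here. The annotation holds no untranslated regions, so an IGORF was placed by its distance to coding sequence: within 200 nt upstream or downstream of a CDS on its own strand, overlapping such a CDS, within 200 nt of a CDS on the opposite strand only, or farther away.

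CPM values (counts per 1000000) were computed for both kinds of feature over the total of CDS counts of the library, from the deposited counts. Log2 ratios used a pseudocount of 1 CPM. Shares have 95% Wilson intervals and other proportions or folds exact binomial intervals. These intervals, and the limit of 3 reads that a count of 0 allows, cover counting error only, since reads without molecular identifiers are not independent molecules. CDSs or IGORFs with a mean of at least 10 reads were compared between the libraries with a two-sided exact binomial test of the split of their counts against the CDS totals, adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. This test compares these libraries beyond counting error, not conditions. The median of each of 14 gene lists was placed among 10000 random CDS lists of the same size. For lists with at least 10 tested genes, the median log2 ratio was also placed among 10000 lists matched on mean CPM in 20 classes. The surroundings of IGORFs were set against 10000 random IGORF sets matched in 5 length classes.

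Scaling factors and common dispersions came from edgeR 4.0.16, and size factors from DESeq2 1.42.0, in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and Biopython 1.88. The binomial test was tested on simulated counts with the dispersion left at counting error. For CDSs it recovered 61% of 200 features changed 1.5-fold, 85% at 2-fold and 92.5% at 4-fold, and called at most 0.183% of unchanged ones. For IGORFs it recovered 0% of 20 at 1.5-fold, 15% at 2-fold and 40% at 4-fold, with 0 false calls. The simulated IGORF reads were split by the CDS totals, so most of them fell in replicate 1. In the data most IGORF reads lay in replicate 2, so these values do not describe the test on the real IGORF counts.

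Named features were chosen by a rule set before the data were examined: the 15 CDSs and 15 IGORFs with the highest mean CPM, the 3 highest members of each list, all members of lists of 7 or fewer genes, and the 5 features with the largest ratio in each direction past the threshold. A gene that this rule names is not reported here. The gene lists, the main tests and most alternatives were also set then, but the lists matched on level, the exchanged IGORF tables, the leader comparison without GCN4 and the tests on CDSs listed at 0 were chosen after data were seen. Alternatives changed the scaling, the minimum count, the pseudocount, the distance to a CDS, the random lists and the libraries used. IGORFs named as neighbours of a gene of a list, those with 10 reads in both libraries, those that hold a CDS and the housekeeping genes named as listed at 0 were chosen after their values were seen. A test that thinned replicate 1 to the depth of replicate 2 was dropped, because thinning leaves a share unchanged by design.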

Results

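Ribosome footprints were counted in 2 replicate libraries of BY4742, a laboratory strain of Saccharomyces cerevisiae of mating type alpha, to ask whether reads are found in open reading frames outside annotated genes. Replicate 1 held 23437283 reads in CDSs and 4057 in IGORFs. Replicate 2 held 2733591 reads in CDSs and 15116 in IGORFs. Replicate 1 thus had 8.57-fold more CDS reads, whereas replicate 2 had 3.73-fold more IGORF reads. A single read corresponded to 0.0427 CPM in replicate 1 and to 0.366 CPM in replicate 2.

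Nearly all counted reads lay in annotated coding sequences. IGORFs took 0.0173% of the counted reads of replicate 1 (95% Wilson interval 0.0168% to 0.0178%) and 0.550% of those of replicate 2 (0.541% to 0.559%), a mean of 0.284% ± 0.377 (SD, n = 2). The SD exceeded the mean, and the intervals of the libraries lay far apart, so no single share describes both. Per 1000000 CDS reads, replicate 1 had 173.1 IGORF reads and replicate 2 had 5529.72, a 31.9-fold difference.

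The typical CDS was read more than the typical IGORF. The median CDS had 537 reads in replicate 1 and 36 in replicate 2, and the median IGORF had 0 in both. At least 1 read was counted in 84.5% and 78.3% of CDSs and in 2.07% and 4.89% of IGORFs, in replicates 1 and 2. IGORFs are short, with a median length of 93 nt and a range of 63 to 1335 nt. Among features of 60 to 300 nt the median was 16 and 1 reads for CDSs and 0 for IGORFs, and 63.7% and 51.4% of the 317 CDSs had a read, against 2.05% and 4.83% of the 78571 IGORFs. At least 10 reads in both libraries were counted for 4474 CDSs, which is 67.1% of those listed. Of the 673 CDS identifiers not found in the R64 annotation, 11.7% and 2.38% had a read, and 3 reached 10 reads in both libraries.

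The CDSs with the most reads encode enzymes of glycolysis and fermentation and parts of the translation machinery. ENO2 (YHR174W, chromosome VIII, 451327 to 452640), the main enolase of growth on glucose, led with 39981 CPM ± 9748 (SD, n = 2). It was followed by PDC1, the main pyruvate decarboxylase, with 34804 ± 8945 CPM, and by the aldolase gene FBA1 with 22620 ± 2843 CPM. YEF3, which encodes the fungal elongation factor 3, had 16648 ± 3624 CPM, and TDH3, a glyceraldehyde-3-phosphate dehydrogenase gene, had 14219 ± 2970 CPM. ADH1, RPS12, PGK1, HSC82, CDC19, EFB1, RPS31 and RPP2A were also among the 15 highest. So was YLR154C-G (chromosome XII, 462522 to 462671, minus strand), which lies inside a copy of the 25S ribosomal RNA gene on the same strand. It had 3304 CPM in replicate 1 and 15427 CPM in replicate 2. The 10 highest CDSs took 15.7% and 21.4% of the CDS reads.

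Of the lists, glycolysis and fermentation and the ribosomal proteins had the highest medians, and those of a-specific, galactose and meiosis genes lay near 0. The 137 ribosomal protein genes took 27.2% and 26.9% of the CDS reads, with a median of 1352 CPM in replicate 1 and 1068 CPM in replicate 2. The 20 genes of glycolysis and fermentation took 14.6% and 19.1%, with medians of 3459 and 3507 CPM. Medians were 486 and 429 CPM for 17 translation factors, 316 and 260 CPM for 37 genes of amino acid biosynthesis, and 363 and 373 CPM for 13 heat shock and stress genes. The highest genes of amino acid biosynthesis were ILV5, of branched-chain amino acid synthesis, with 6922 ± 327 CPM, the glutamine synthetase gene GLN1 with 2466 ± 807 and LEU1 with 1600 ± 566. Among heat shock and stress genes, the chaperone genes HSC82, SSA2 and SSB1, which are also expressed in unstressed cells, were highest, with 9829 ± 3369, 5534 ± 519 and 3838 ± 692 CPM. The 10 nuclear genes of respiration, which glucose represses, had medians of 84.95 and 70.4 CPM, led by ATP1 with 308 ± 20.3, ACO1 with 212 ± 88.2 and ATP2 with 195 ± 7.79 CPM. These medians depend on how a gene is counted. With near-identical copies summed, ribosomal proteins had 2709 CPM in place of 1210 (means of the medians of the libraries) and translation factors 696 in place of 457. Per kilobase of coding sequence the values were 3027 for ribosomal proteins and 191 for heat shock genes, the latter in place of 368. The paralogs TEF1 and TEF2, EFT1 and EFT2, and TIF1 and TIF2 share nearly all of their sequence, and the split of reads within each pair is uncertain.

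Of the alpha-specific genes, 3 were read above the median of all CDSs and STE3 below it, and a-specific genes were hardly read at all. The 4 alpha-specific genes had medians of 690 and 530 CPM. MF(ALPHA)2 and MF(ALPHA)1, which encode the alpha pheromone, had 1947 ± 236 and 1181 ± 219 CPM. The agglutinin gene SAG1 had 39.3 ± 7.53 CPM and the a-factor receptor gene STE3 had 8.38 ± 3.05 CPM. The 6 a-specific genes had medians of 0.128 and 0 CPM. Of these, STE6 had 18 and 2 reads, BAR1 15 and 0, MFA1 5 and 0, STE2 1 and 1, MFA2 1 and 0, and AGA2 was listed at 0 in both.

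Among the markers deleted in BY4742, URA3 was listed at 0 in both libraries, LEU2 had 1 and 0 reads, and LYS2 had 2 and 0. HIS3, of which the strain carries a partial deletion, had 1046 and 116 reads, or 43.5 ± 1.55 CPM (SD, n = 2). Which part of HIS3 these reads cover was not analysed here, and sequence left by the deletion would be counted. The galactose genes GAL1, GAL2, GAL7 and GAL10 had 0, 6, 4 and 5 reads in replicate 1 and 0 in replicate 2. The 15 genes of meiosis and sporulation had medians of 0.725 and 0 CPM. The highest by mean were IME1, the inducer of meiosis, with 3.01 ± 0.397 CPM, ZIP1 with 2.87 ± 0.952 and SPS4 with 108 reads in replicate 1 and 1 in replicate 2; in replicate 1 alone their order was reversed, with 2.73, 3.54 and 4.61 CPM. Of the proposed de novo genes, BSC4 was listed at 0 and MDF1, annotated as FYV5, had 1 and 0 reads. None of the 7 mitochondrially encoded genes was found among the identifiers, and they were not analysed here. A value of 0 cannot be read as lack of translation, because the housekeeping genes HYP2, LSM8 and TIM9 were also listed at 0 in both libraries.

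Of the 13 lists found, 11 had a median outside the central 95% of random lists, on the same side, in both libraries. The other lists were galactose utilisation, at 2.935 and 1.62, and the upstream-ORF controlled genes GCN4 and CPA1, at 84.9 and 61.1. The respiration genes at 97.62, the marker genes at 2.135 and the proposed de novo genes at 2.355 in replicate 1 lay close to these bounds. With 2000 random lists in place of 10000 the number was 9.

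**Figure D1:**
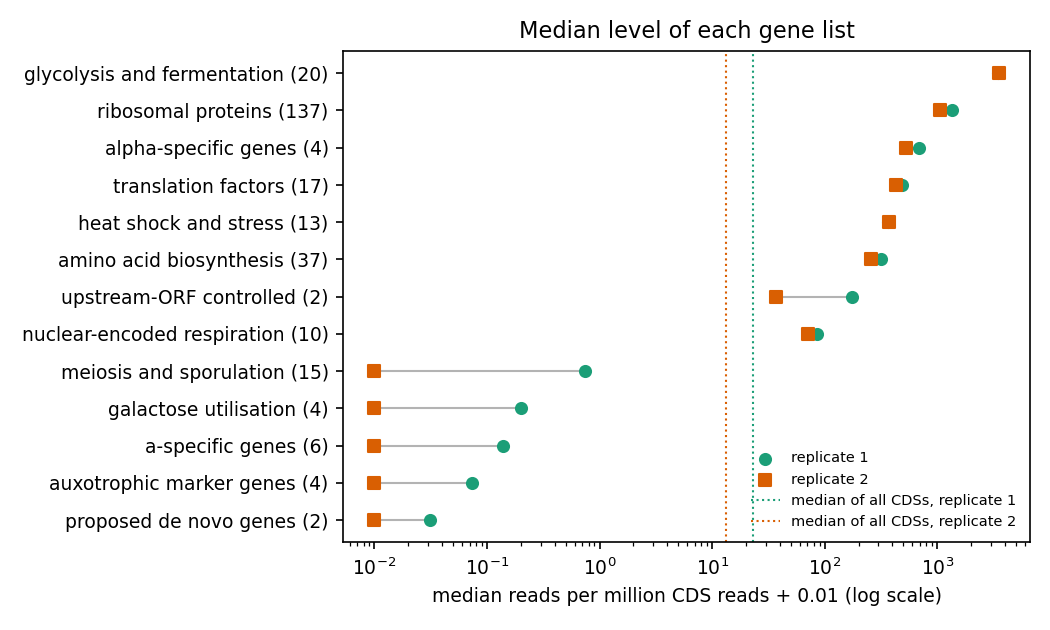
Median CPM plus 0.01, on a log axis, for each of 13 gene lists (number of genes in brackets) in replicate 1 (circles) and replicate 2 (squares). Dotted lines mark the median of all 6666 CDSs, 22.9 and 13.2 CPM; glycolysis and ribosomal proteins lie far above it and 5 lists lie near 0.

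The libraries ranked CDSs alike but differed beyond counting error. Across 5131 CDSs with a mean of at least 10 reads, log2 CPM correlated with Pearson's r = 0.972 and Spearman's rho = 0.968; genes are not independent replicates. The exact binomial test with Benjamini-Hochberg adjustment separated 3652 of these CDSs, of which 372 were higher and 3280 lower in replicate 2. The median log2 ratio was -0.61, or 0.657-fold, so most of this imbalance is a shift in 1 direction across CDSs, called the shared shift here. Its size varied with level, with a median of -0.22 in the highest of 5 equal classes by mean CPM and -0.69 in the lowest. With edgeR's TMM scaling 2279 CDSs differed, 1248 higher and 1031 lower, and with DESeq2's size factors 2263 differed, 1317 higher and 946 lower. The biological coefficient of variation estimated by edgeR was 27.3% with TMM scaling and 40.2% with CDS totals.

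Genes of glycolysis and fermentation were higher in replicate 2 relative to the shared shift. Of the 20, 14 were higher and 1 lower in replicate 2, and all 20 lay above the median ratio of all CDSs. CDSs of the highest level had higher ratios than the rest, so the list was also set against 10000 random lists matched on mean CPM. In this comparison, chosen after the data were seen, its median log2 ratio, 0.27, stood at percentile 99.81 (95% of lists from -0.36 to 0.13). The highest of the 20 classes has no upper limit, so the match may leave part of the effect of level. This holds for every list with genes in that class. Of 137 ribosomal protein genes, 40 were higher and 86 lower by CDS totals, but 97 lay above the median ratio, so their direction depends on the scaling. Their median log2 ratio of -0.24 lay below all of the lists matched on level. Those lists drew on the few other CDSs of the highest classes, so they overlapped and spread little (95% of lists from -0.024 to 0.045). Lists matched to glycolysis could hold ribosomal protein genes, and the reverse, so the results of both groups are not independent. Among heat shock genes 7 were higher and 1 lower, among genes of amino acid biosynthesis 10 were higher and 21 lower, and among respiration genes 0 were higher and 6 lower. Yet 28 of the 37 amino acid biosynthesis genes and 6 of the 10 respiration genes lay above the median ratio, so these directions too depend on the scaling. Against lists matched on level the heat shock genes stood at percentile 99.72, the translation factors at 92.7, amino acid biosynthesis at 73.6 and respiration at 72.9. All 4 alpha-specific genes were lower by CDS totals, and 3 of them lay above the median ratio.

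The largest ratios in favour of replicate 2 were those of YDR445C, with 217 and 154 reads (6.08-fold, 95% interval 4.92 to 7.51), YLR154C-G (4.67-fold), YDR278C with 155 and 85 reads (4.70-fold, 3.57 to 6.16), PBI2, an inhibitor of vacuolar protease B (2.66-fold, 2.33 to 3.04), and ARO8, an aromatic aminotransferase (2.60-fold, 2.52 to 2.69). Of these, YDR445C and YDR278C are among the 673 identifiers not found in the R64 annotation, and YLR154C-G lies inside a ribosomal RNA gene. In the other direction stood SMP1, a MADS-box transcription factor, with 123 and 0 reads, the histone acetyltransferase gene RTT109 with 223 and 2 reads, SLS1 with 481 and 7, IZH4 with 731 and 12, and MIG2, a glucose repressor, with 3547 and 69.

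GCN4, the transcriptional activator of amino acid biosynthesis that is known to be controlled by short upstream ORFs, had 7855 reads in replicate 1 and 180 in replicate 2. This is 335 against 65.8 CPM, or 0.196-fold (95% exact interval 0.169 to 0.228, adjusted p = 1.56e-178 by the exact binomial test), and relative to the median ratio of all CDSs its log2 ratio was -1.72. CPA1, a subunit of carbamoyl phosphate synthetase whose leader encodes a regulatory peptide, had 423 and 23 reads, or 0.466-fold (0.292 to 0.709). Its log2 ratio was -1.02, or -0.41 relative to the median ratio, and its interval includes the shared shift of 0.657-fold. With the tables paired as labelled, IGORFs that end within 200 nt upstream of GCN4 went the other way. They had 10 reads in replicate 1 and 243 in replicate 2, or 0.427 and 88.9 CPM. With the IGORF tables exchanged between the libraries these would be 10.4 and 3.66 CPM, the same direction as the CDS. IGORFs farther upstream are not in these counts, so the values need not hold for the whole leader of GCN4. As labelled, the CPM upstream of GCN4 was 208-fold higher in replicate 2. All IGORFs together were 31.9-fold higher and those upstream of CDSs 30.2-fold, so part of the contrast is not particular to GCN4. In replicate 2 most of the reads upstream of GCN4, 192, lay in the IGORF on chromosome V from 139928 to 140011, minus strand. It had 4 of the 10 in replicate 1 and ends 164 nt before the GCN4 start codon. Its stop-to-stop translation is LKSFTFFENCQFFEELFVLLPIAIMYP, closing with an ATG and a short ORF.

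**Figure D2:**
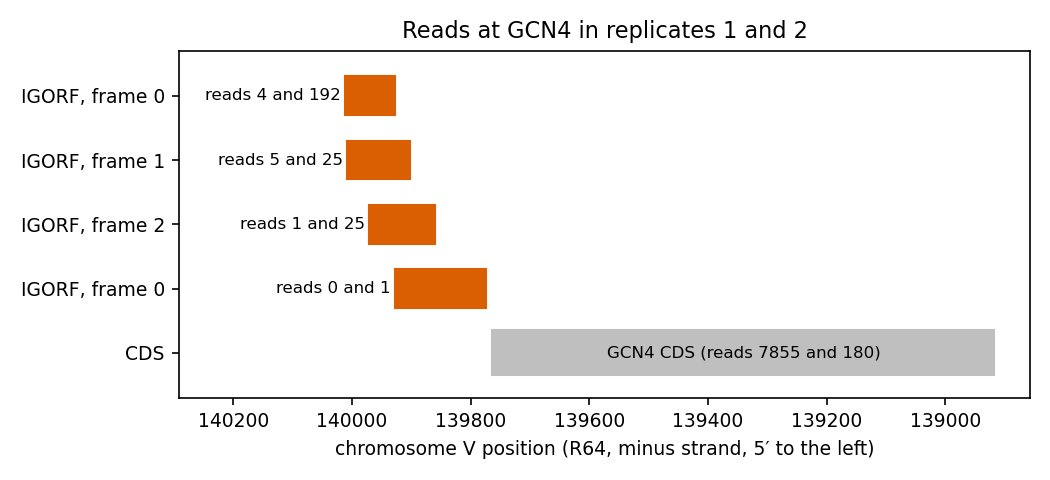
Map of the GCN4 coding sequence (grey) and the 4 IGORFs with reads that end within 200 nt upstream of it (orange). Both lie on the minus strand of chromosome V, with the reads of replicates 1 and 2 printed beside each. With the tables paired as labelled, the CDS had 7855 and 180 reads and the IGORF from 139928 to 140011 had 4 and 192; the opposite direction would be lost with the IGORF tables exchanged.

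Few IGORFs had more than scattered reads. At least 10 reads were counted for 38 IGORFs in replicate 1 and 190 in replicate 2, and for 29 in both, against 0.0914 if the libraries were independent. The 29 are 0.0367% of all IGORFs (95% exact interval 0.0246% to 0.0527%). At least 30 reads were counted for 8 and 49 IGORFs, and for 5 in both. Of the 199 IGORFs that reached 10 reads in either library, 161 did so in replicate 2 only.

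Among the 96 IGORFs with a mean of at least 10 reads the libraries correlated weakly, with r = 0.442 and rho = -0.01. Without the IGORF with the most reads r was 0.033. Choosing IGORFs by the mean of both libraries can itself lower the correlation, so the low values may be partly built in. Among 1083 CDSs with mean reads in the same range r was 0.733, but their reads lay mostly in replicate 1 and those of the IGORFs mostly in replicate 2, so the counts per library were not alike. The exact binomial test separated 93 of the 96 IGORFs, and all 93 were higher in replicate 2 per CDS read, which largely restates the 31.9-fold difference in total. The number that differ, the size of the difference and the direction of some IGORFs rest on the pairing of the tables. With the IGORF tables exchanged between the libraries, 37 of the 96 differed, 32 higher and 5 lower with the CDS table of replicate 2, and the difference in total was 2.30-fold.

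**Figure D3:**
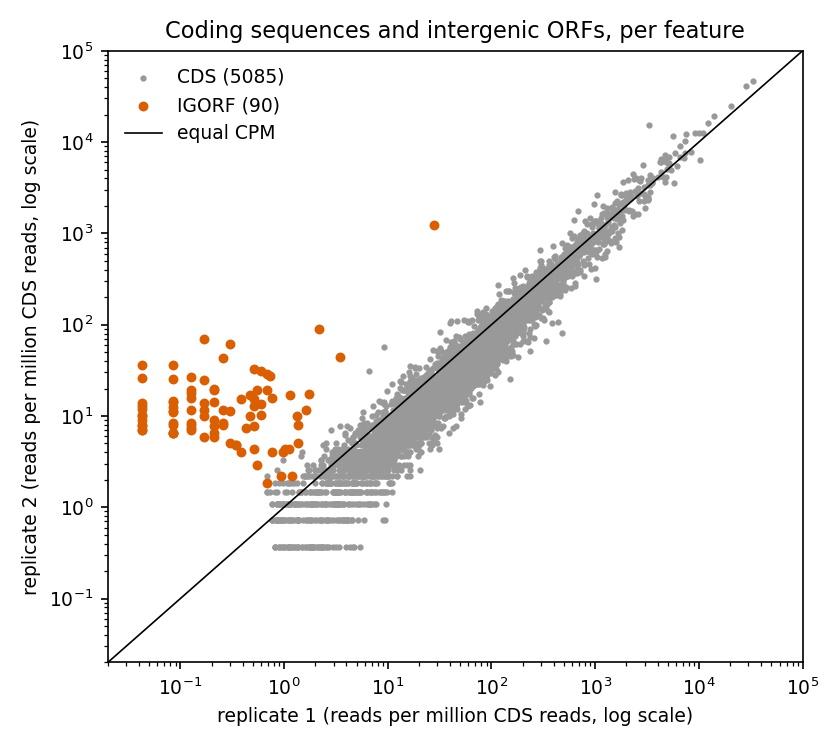
CPM over the CDS total in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, for the 5085 CDSs (grey) and 90 IGORFs (orange) with a mean of at least 10 reads and a read in both libraries. The line marks equal values; most CDSs lie below it, with a median log2 ratio of -0.61, and all 90 IGORFs lie above it with the tables paired as labelled.

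IGORFs with reads lay upstream of genes more often than IGORFs at large. Of the 29 IGORFs with at least 10 reads in both libraries, 17 lay within 200 nt upstream of a CDS on the same strand, or 58.6%, against 19.5% of all IGORFs; random sets of matched length held 5.69 on average and at most 14. Another 6 overlapped the start of a CDS on their strand by at most 7 nt, where random sets held 0.319 overlaps with a CDS of any extent. None lay within 200 nt downstream of a CDS, where random sets held 4.55. Near a CDS on the opposite strand lay 2, and 4 lay farther from any CDS. Upstream IGORFs took 59.97% and 56.7% of all IGORF reads. With a distance of 100 nt, 41.4% of the 29 and 11.3% of all IGORFs counted as upstream, and with 50 nt 27.6% and 5.87%.

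**Figure D4:**
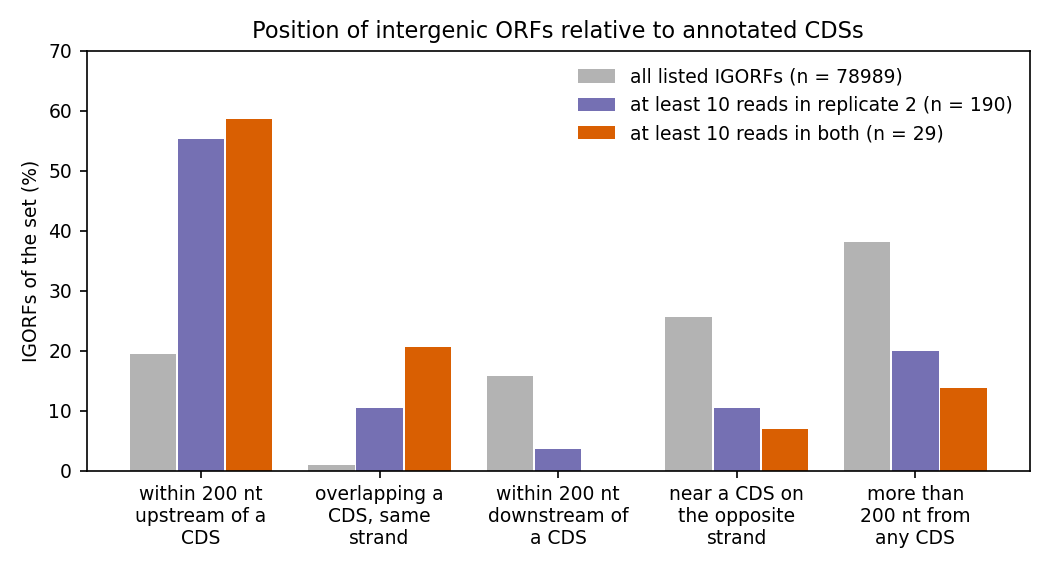
Share of IGORFs (percent) in each position relative to annotated CDSs, for all 78989 IGORFs (grey), the 190 with at least 10 reads in replicate 2 (violet) and the 29 with at least 10 reads in both libraries (orange). The upstream position holds 19.5%, 55.3% and 58.6% of these sets.

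The IGORF with the most reads lies on the plus strand of chromosome XV, from 619721 to 619789, and ends 50 nt upstream of PDR5, which encodes a multidrug transporter. It had 658 and 3344 reads, 16.2% and 22.1% of all IGORF reads, and with the tables paired as labelled a 43.6-fold higher CPM in replicate 2 (95% exact interval 40.1 to 47.4). With the IGORF tables exchanged it would have 143 and 241 CPM, a 1.69-fold difference. Its 69 nt read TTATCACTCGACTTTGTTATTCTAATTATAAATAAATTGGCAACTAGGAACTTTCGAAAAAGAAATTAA and hold no in-frame ATG. The ranks below it are by mean CPM with the tables paired as labelled, which replicate 2 dominates. With the IGORF tables exchanged, 6 of the 15 highest would stay among them, and in replicate 1 alone 3. The next lies on chromosome III, from 238921 to 239025, 29 nt upstream of CPR4, a cyclophilin gene, with 51 and 243 reads; with the tables exchanged, or in replicate 1 alone, the one on chromosome XIII from 297088 to 297192 (81 and 122 reads) would precede it. Others among the 15 highest lie upstream of the GTPase gene SEC4 (16 and 78 reads), the iron-sulfur protein gene ISA1 (17 and 75), the prefoldin gene PFD1 (2 and 100) and NRD1, a factor of transcription termination (3 and 73). The IGORFs at PFD1 and NRD1 rank high through replicate 2 only, and with the tables exchanged they would rank 36 and 41. The IGORF at the start of MF(ALPHA)1, chromosome XVI from 193475 to 193651, had 2 and 70 reads.

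Further members of the 29 lie upstream of the actin gene ACT1 (16 and 52 reads), of ACC1, acetyl-CoA carboxylase (41 and 48), of the zinc transporter gene ZRT2 (18 and 43) and of the GTPase gene RHO1 (14 and 37). An in-frame ATG was present in 44.0% of all IGORFs, in 51.7% of the 29, in 42.1% of the 38 with 10 reads in replicate 1 and in 64.2% of the 190 with 10 reads in replicate 2. The 29 had a median length of 96 nt and a median GC content of 35.8%, near the 93 nt and 35.7% of all IGORFs. The 190 were longer, with a median of 109.5 nt, and the shares with an ATG were not matched on length.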

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

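The alternatives with distances of 50, 100 and 500 nt, surroundings and read levels by single library, exchanged IGORF tables (for the share, the IGORFs that differ, the named and highest IGORFs and the leader comparison), the leader comparison without GCN4, lists drawn from annotated CDSs and 2000 random lists were chosen only after the data were seen. The scalings left the sign of the features named for their ratio, but among genes of the short lists MF(ALPHA)2 turned from -0.25 to 0.35 with TMM and 0.38 with DESeq2, MF(ALPHA)1 from -0.38 to 0.22 and 0.25, SAG1 from -0.38 to 0.20 and 0.23 and HIS3 from -0.07 to 0.51 and 0.54, by the shared shift. STE3 and CPA1 kept their sign but passed the threshold with neither. With the IGORF tables exchanged, IGORFs that differ became 37, and of the 5 named for their ratio 4 turned: on chromosome V from 139928 (-1.90) and 15877 (-0.91), XI from 431279 (-1.19) and IV from 699887 (-1.94). The majority of CDSs that differ turned with the scaling, from 10.2% higher in replicate 2 to 54.8% with TMM (2279 CDSs) and 58.2% with DESeq2 (2263 CDSs). The number of gene lists beyond the bounds, 11, ranged from 9 to 12; with random lists of annotated CDSs it was 11, but respiration left (95.95 in replicate 1) and galactose utilisation entered. The 29 IGORFs at 10 reads became 38 to 190 with a single library, 199 in either library, 256 in the sum, 74 at a minimum of 5, 8 at 20, 15 without IGORFs within 50 nt of a CDS, and 2 with replicate 1 thinned to the CDS depth of replicate 2. The 5 at 30 reads became 8 to 49, 52, 62, 3 and 1 for the single libraries, either, the sum, the 50 nt rule and thinning. The correlation of CDSs was 0.981 with no filter, 0.969 at a mean of 50 reads and 0.965 with a pseudocount of 0.1, and that of IGORFs (0.442, bootstrap interval -0.20 to 0.74) was 0.891 at a mean of 50 reads over 9 IGORFs only, 0.517 with no filter and 0.245 with a pseudocount of 0.1. IGORFs that differed were 1353 of 4596 tested with no filter and 9 of 9 at a mean of 50 reads. The gap between CDS and IGORF reads, 286.5 by medians, was 1963 by means and 8.5 by medians among features of 60 to 300 nt. IGORFs upstream of a CDS were 27.6% with a distance of 50 nt, by the narrower window. Where no cause is named, the cause was not tested. No paired analysis was possible because the series has 1 group. No IGORF is mitochondrial, so leaving such IGORFs out removed none. Replicate correlations cannot be had without either replicate. The depth of replicate 1 in IGORFs, 4057 reads, limits every statement on IGORFs found in both libraries.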

Other observations

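The tests on CDSs listed at 0 were chosen only after examples had been seen, the test of exchanged tables was prompted by GCN4, which was left out of it, and the leader comparisons with exchanged tables and without GCN4 also came later. Some IGORFs are parts of genes in the R64 annotation. An overlap in frame with an annotated CDS was found for 7 IGORFs. The one holding YDL204W-A (chromosome IV, 94028 to 94285, plus strand) had 5 and 52 reads, and the one holding YMR106W-A (chromosome XIII, 480921 to 481187, plus strand) had 2 and 34. Within 200 nt of a tRNA, rRNA, snoRNA or snRNA gene on their strand lay 1 of the 29 IGORFs with 10 reads in both libraries, 8 of the 190 with 10 reads in replicate 2 (4.21%) and 1.74% of all IGORFs. Examples among the 15 highest are SNR78, at 85 nt from the IGORF on chromosome XIII from 297088 to 297192 (81 and 122 reads), SNR87, at 140 nt from the one on chromosome XI from 431279 to 431407 (7 and 167 reads), and SNR60, at 99 nt from the one on chromosome X from 349333 to 349431 (1 and 72 reads). In 175 of 791 nested IGORF pairs of replicate 1 and 354 of 1907 of replicate 2 the inner ORF had more reads than the outer, so the counts are not a plain overlap of reads with each ORF.

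The 31.9-fold higher number of IGORF reads per CDS read in replicate 2 was present upstream of CDSs (30.2-fold), downstream (39.6-fold), in overlaps with a CDS (25.3-fold), near CDSs of the opposite strand (42.5-fold) and away from them (34.1-fold), and was 28.1-fold without the 10 IGORFs with the most reads in replicate 2. Reads of coding sequences counted in touching IGORFs would leave distant IGORFs alike in both libraries. With the tables paired as labelled, those more than 200 nt from any CDS of their strand differed 36.3-fold (95% bootstrap interval 31.3 to 41.6). This argues against such reads for the labelled pairing only. With the IGORF tables exchanged all IGORFs would differ 2.30-fold, and the distant ones were not tested. Fragments of mRNA outside ribosomes were predicted to raise leaders and 3′ ends alike. The gain per kilobase was 9.52 times larger upstream than downstream (4.57 to 19.5), and 5.77 times without the IGORF at PDR5. However, upstream IGORFs already led in replicate 1, with 104 CPM against 6.36 CPM downstream. An equal fold rise would thus also give a larger gain upstream, and by fold the downstream IGORFs rose no less. This test, made with the tables as labelled, therefore cannot decide on fragments of mRNA. An exchange of the CDS or IGORF tables of the libraries may also be considered: it would bring the shares to 0.0645% and 0.148%, but across 132 genes the ratios of leader and CDS reads correlated with rho = 0.041 (-0.13 to 0.20), so an exchange cannot be told apart from tables as labelled. No biological explanation was tested, since the design has 1 group.

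CDSs of low level were lower in replicate 2 than CDSs of high level. The median log2 ratio was -0.69, -0.80, -0.73, -0.58 and -0.22 from the lowest to the highest of 5 equal classes by mean CPM, a difference of 0.47 between the ends (95% bootstrap interval 0.41 to 0.52). A few abundant CDSs taking more of the counts were not tested by TMM scaling. TMM applies 1 factor to all CDSs of a library and so could not remove the difference (0.61 after it). The change from 0.47 to 0.61 arose through the pseudocount of 1 CPM. With a pseudocount of 0.1 CPM the difference after TMM was 0.68, so its size depends on the pseudocount. After the median of 20 bins of GC content was subtracted, the difference by CDS totals was 0.42 (0.35 to 0.47). After 20 bins of coding length it was 0.44 (0.37 to 0.50), so neither accounts for most of the difference. Other sources were not tested.

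Of the 5993 annotated CDSs, 436 were listed at 0 in both libraries. Among CDSs with at least 50% of their length under another annotated CDS, 92.6% of 81 were at 0 (95% exact interval 84.6% to 97.2%), such as LSM5. Some of the 81 also lack unique sequence, and of the 36 with mostly unique sequence 83.3% were at 0 (67.2% to 93.6%). Among CDSs with under 10% of their 28-mers found once in the genome, 78.9% of 199 were at 0 (72.6% to 84.3%). Among CDSs with unique sequence and no overlap with another annotated CDS the value was 3.30% of 5419. Counting rules for overlaps and repeats may thus account for many of the zeros. HYP2, TIM9, LSM8, ESS1 and DAD4, with mostly unique sequence and no overlap with another annotated CDS, were among 179 left at 0. Overlaps with the 673 identifiers without a position could not be seen. A counting rule for overlaps is thus not excluded for these 179, and the source of their zeros stays open.

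With the tables paired as labelled, GCN4 raised the hypothesis that genes with reads in the leader in replicate 2 have a lower CDS level there. The 86 tested CDSs within 200 nt downstream of an IGORF with at least 10 reads in replicate 2 had a median log2 ratio of -0.61, against -0.50 in lists matched on mean CPM (95% of lists from -0.64 to -0.36). This is percentile 4.83 of 10000 lists, not under the 2.5 set beforehand. GCN4, which prompted the test, is among the 86; without it the median was -0.60 and the percentile 8.44. Missing this bound does not exclude a small shift, so whether the pattern of GCN4 is general stays open. With the IGORF tables exchanged, 22 CDSs had a median of -0.63 against -0.53 in matched lists (-0.79 to -0.27), percentile 23.8.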
